A study of Mus musculus with 7 samples.

How the data were processed

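The 7 RNA-seq libraries were made from total RNA of mouse incisor cervical loop epithelium with the Illumina TruSeq RNA protocol, per the labels' protocols. Groups were taken from the treatment label: 3 libraries without tamoxifen (control, replicates 1, 2 and 7) and 4 with tamoxifen (mutant, replicates 3, 4, 5 and 9), all K14CreER;Srsf1fl/fl. No batch is given in the labels, and no replicate number is shared between the groups.

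Per the submitters' processing notes, Bowtie, TopHat, SAMtools and DESeq were used, with no versions given, and the series text states that JuncBASE identified and quantified the splicing events. The read counts behind the events were not used here. The authors deposited a table of 278 events with PSI as a percent from 0 to 100 in each library, the median percent of each group and the difference of the medians, per the file headers. JuncBASE derives PSI from reads that support the inclusion and exclusion forms, and PSI from few reads is imprecise, but no read number per event is given. The authors' deposited table also gives a raw and a corrected p-value from JuncBASE and a raw and a corrected p-value from DRIMSeq, a test of isoform proportions, per the file headers. The test behind the JuncBASE p-value is not given in the sources used here. All 278 corrected DRIMSeq p-values are below 0.1, with a maximum of 0.0979, so the table is a selected one. Medians recomputed from the library columns matched the deposited ones within 0.005 points and their differences within 0.01 points. All 7 library columns were assigned to a sample by title, and 0 columns of per-sample values were left unused.

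The submitters' notes name mm9. Of 863 distinct junctions in the table, 650 (75.3%) coincide exactly with an intron of GENCODE M21, an annotation of GRCm38 (mm10), and so do 377 of the 405 junctions (93.1%) of events that the table classes as known, against 0 after a shift of 1000 bases. Coordinates were therefore read as GRCm38, and exon annotation was taken from M21. The table classes 150 events as using only known junctions and 128 as having at least 1 junction outside its annotation. All listed cassette exons (100%) are M21 exons. For 26 events the gene name in the table does not match the M21 gene at the event, through older symbols, joined names of neighbouring genes, or an event that lies in another gene. Gene names are those of the table, except that the joined name of Elp3 and Ccser2 is given as Elp3, where the splice site lies. Events that overlap on the genome fall into 234 groups.

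The table gives PSI without counts, so the test written for that case before the data were examined was used: limma 3.58.1 in R 4.3.3 on PSI in percentage points, mutant against control, with the spread moderated across events and Benjamini-Hochberg adjustment over the 278 events at 0.05. Directions and sizes are differences of group medians, as deposited, except where a limma difference of means is given with its SE. Means and medians differed in sign for 0 events. The median absolute difference between libraries was 1.94 to 2.92 points for pairs of controls, 3.32 to 5.89 points for pairs of mutants and 9.95 to 17.2 points between groups, and at most 5.04% of events had identical values in a pair, so each library was counted as a separate sample. The limma step was tested on simulated PSI for 278 events in 20 simulations: it called 21.6% of events changed by 5 points, 67.6% of those changed by 10, 92.6% of those changed by 20 and 1.39% of unchanged events, with a false discovery rate of 2.94%. Simulated noise was normal, with the same SD in both groups, without the bounds of PSI and without selection of events. These rates therefore need not hold for the selected events of the real data.

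Shares of events were tested with exact two-sided binomial tests against 50%, and the share of exons with a length divisible by 3 against 33.3%. Intervals of shares are exact Clopper-Pearson 95% intervals. Events of one gene are not independent. Sizes were compared between cassette exons and each other type with two-sided permutation tests of the difference of medians (100000 resamples), with Benjamini-Hochberg adjustment over the 7 types. For motif counts, exon sequences were taken from the M21 transcripts, with 1 cassette exon per group of overlapping events, and tested with two-sided permutation or sign-flip tests (100000 resamples). Bootstrap intervals resampled genes 10000 times. Summaries used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

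Named events followed a rule fixed before the data were examined: among events past the limma threshold, the 12 largest gains and the 12 largest losses by difference of medians, with each gene represented by 1 event, its largest change in either direction; every Srsf1 event; and up to 4 genes of each of 13 fixed lists with the largest absolute difference. This gave 40 events in 40 genes, of which 36 have control and mutant values that do not overlap. Exceptions are named where they occur. Some of the named events are not reported here. The lists, also fixed beforehand and partly overlapping, hold 593 genes: SR proteins and related factors (29 genes), hnRNPs and other splicing regulators (48), core spliceosome (40), textbook SRSF1-dependent genes (28), cell cycle (65), DNA replication and repair (64), cell death (41), dental epithelial progenitor and lineage genes (42), cervical loop signalling (76), adhesion, cytoskeleton and epithelial isoforms (71), chromatin and transcription (68), and 2 lists of other cell types, dental mesenchyme (22) and blood or endothelium (20).

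Alternatives fixed beforehand were the logit of PSI held within 1 to 99%, a minimum change of 5 or 10 points, an adjusted p of 0.01, the authors' JuncBASE and DRIMSeq corrected p-values, known junctions only, 1 event per gene, means in place of medians, and leaving out each library in turn. Alternatives chosen after seeing the data were a control PSI of 20 to 80%, 1 event per group of overlapping events, all event types other than first, last and mutually exclusive exons, and, for the direction of cassette exons, known junctions, the DRIMSeq threshold and leaving out each library.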

Results

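RNA-seq measured alternative splicing in the epithelium of the incisor cervical loop, the growing end of the mouse incisor where dental epithelial progenitors reside. All 7 libraries came from K14CreER;Srsf1fl/fl mice aged 8 to 10 weeks, in which tamoxifen activates a Cre recombinase in keratin 14-expressing epithelium and deletes loxP-flanked Srsf1 sequence. SRSF1 is an SR protein, a splicing factor that binds exons and usually promotes their inclusion. The 3 control libraries (replicates 1, 2 and 7) came from mice without tamoxifen, and the 4 mutant libraries (replicates 3, 4, 5 and 9) from induced mice. The data were percent spliced in (PSI) values for 278 alternative splicing events under 228 gene names. PSI is the percentage of an event's reads that support the inclusion form. The series text gives an estimated total of 648000000 reads aligned uniquely to mouse cDNA, and speaks of 7 samples in 4 conditions, whereas the labels give these 2 groups. Depth per library and per event is unknown, so no counting interval can be attached to a PSI value. Unless stated otherwise, values are the mean ± SD over the 3 control and the 4 mutant libraries, and coordinates are on GRCm38. The labels do not state whether each library came from a separate animal, so the limma p-values measure only the spread between these samples. Binomial, Fisher, permutation and sign-flip tests took events or exons as units, and their p-values measure no spread between samples.

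The targeted gene was examined first. The one event listed for Srsf1 rose from a PSI of 7.97% ± 2.12 (SD, n = 3) in the controls to 62.9% ± 17.3 (SD, n = 4) in the mutants. In this event, the 5′ splice site of Srsf1 exon 1 is joined to exon 2 of Vezf1, the neighbouring gene on the same strand, which encodes a zinc finger transcription factor. The exclusion form joins it to either of 2 downstream Srsf1 exons or, past the end of Srsf1, to an exon of Gm15892 at 88066358 to 88066503. The inclusion junction spans chromosome 11 from 88048033 to 88073056 and skips all Srsf1 exons after the first. It ends at the coding exon of Vezf1 (ENSMUSG00000018377.10) at 88073057 to 88073751, and Vezf1 itself begins 14524 bases past the end of Srsf1 (ENSMUSG00000018379.17). Control libraries 1, 2 and 7 had PSI values of 5.83%, 8.00% and 10.07%. Mutant libraries 3, 4, 5 and 9 had 65.60%, 44.74%, 85.52% and 55.83%, so all 4 lay above all 3 controls. The difference was 55.0 percentage points (SE 8.30, limma adjusted p = 0.00118), and the authors' deposited table gives a DRIMSeq corrected p of 6.07e-11. The table holds no expression values, so the level of Srsf1 RNA could not be compared.

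**Figure D1:**
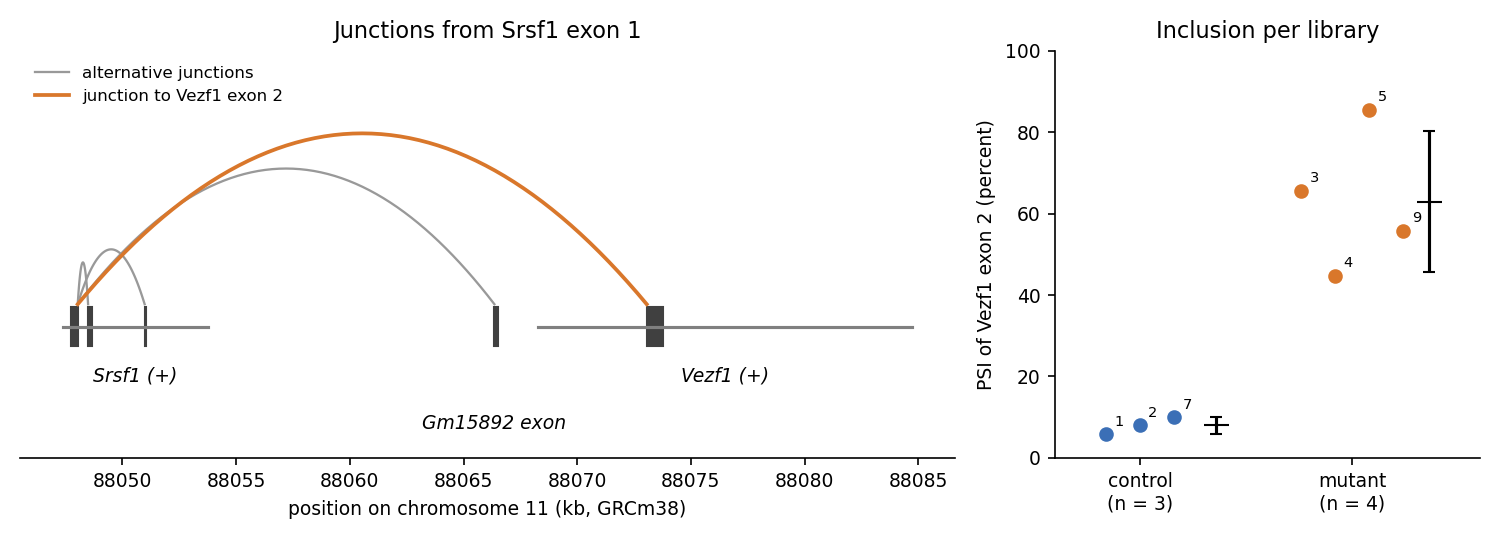
Left, junctions that leave Srsf1 exon 1 on chromosome 11 (kb, GRCm38), with the Srsf1 and Vezf1 gene spans as grey lines and the exons joined as dark boxes. Right, PSI (percent) of Vezf1 exon 2 among the junctions that leave Srsf1 exon 1, in each numbered library with the mean and SD beside it. The 4 mutants lie between 44.74% and 85.52% and the 3 controls between 5.83% and 10.07%.

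The comparison of mutant with control libraries asks which exons, introns and splice sites are used differently in this epithelium after tamoxifen induction of the Srsf1 deletion. All 7 libraries share the genotype, so an effect of tamoxifen itself cannot be separated from that of the deletion. Inclusion fell far more often than it rose. Of the 278 listed events, 266 passed the limma test at an adjusted p of 0.05. In the authors' deposited table, 1 event had a JuncBASE corrected p below 0.05. Such counts are not like for like, because the limma adjustment covered only the 278 listed events. A Fopnl exon, chosen after its values were seen, had a raw JuncBASE p of 3e-05 and a corrected p of 0.150. A Benjamini-Hochberg adjustment over 278 tests could not give so large a corrected value. Among the 266 events past the limma threshold, 219 fell and 47 rose in the mutant, which is 82.3% lower (exact 95% confidence interval 77.2 to 86.7%, exact two-sided binomial p = 1.02e-27). The 266 events carried 218 gene names. The median absolute change was 13.7 points over the changed events, with a range from 3.80 to 52.71 points, while the median SD between libraries of one group was 2.40 points in the controls and 4.22 points in the mutants. Control and mutant values did not overlap in 266 of the 278 events, where chance gives 5.71%, and 254 events both passed the test and had separate groups. These counts describe a selected table, because every listed event has a DRIMSeq corrected p below 0.1 in the authors' deposited table. The limma result is therefore not independent evidence that an event changed, and events or genes that are not listed cannot be called unchanged.

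Cassette exons, which are spliced in or skipped as a unit, made up 169 of the changed events (63.5%). Among them, 143 fell and 26 rose (84.6% lower, exact 95% confidence interval 78.3 to 89.7%, exact two-sided binomial p = 8.94e-21). All 61 changed cassette exons with a control PSI of at least 95% fell, and 44 of these involved a junction that the authors' deposited table does not class as known. Among the 56 with a control PSI from 20 to 80%, which had room to move both ways, 40 fell and 16 rose (71.4% lower, exact two-sided binomial p = 0.00184). The remaining types were 26 alternative first exons (20 lower, exact p = 0.00936), 25 alternative last exons (22 lower, exact p = 0.000157), 17 retained introns (11 lower, exact p = 0.332) and 8 coordinate cassettes, in which adjacent exons are skipped together (8 lower, exact p = 0.00781). There were also 8 alternative 5′ splice sites (6 lower, exact p = 0.289), 7 mutually exclusive exon pairs (4 lower, exact p = 1) and 6 alternative 3′ splice sites (5 lower, exact p = 0.219). For first, last and mutually exclusive exons, the form called inclusion is a convention of the table, so their direction tests do not show that inclusion fell. Some switches were also listed in both directions, as for last exons of Fyttd1 (13.79 and −14.59 points) and Cdc123 (8.52 and −8.68 points). So were first exons of Wfdc2 (19.37, −16.09 and −19.28 points). The mutually exclusive exons that rose were all versions of 1 Dlg1 switch. Without these types, a setting chosen after seeing the data, 173 of 208 changed events fell (83.2%). That share is not free of the same limit, because 5′ splice sites of Gpbp1 were listed in both directions (12.13 and −12.05 points). It also counts retained introns, where lower inclusion means more removal of the intron. The median absolute change was 13.6 points for cassette exons, 17.5 points for retained introns and 21.6 points for alternative 3′ splice sites. Neither type differed from cassette exons after adjustment over the 7 comparisons (two-sided permutation p = 0.0681 and 0.0354, both with adjusted p = 0.238), and the other 5 types had adjusted p = 0.877.

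**Figure D2:**
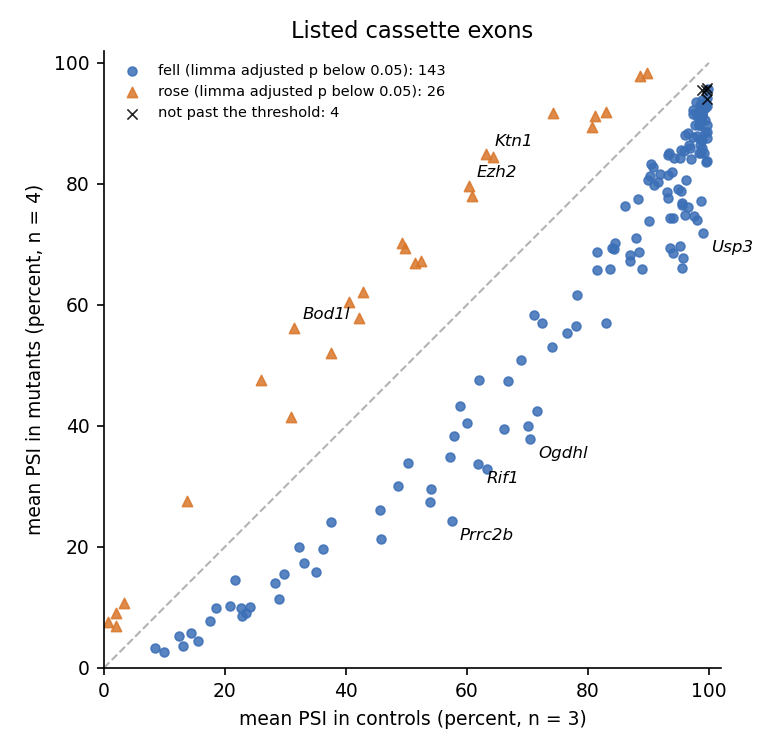
Mean PSI (percent) of each of the 173 listed cassette exons in the 3 controls (horizontal axis) against the 4 mutants (vertical axis), with the line of equal PSI dashed. Of these, 143 exons fell and 26 rose at a limma adjusted p below 0.05, and 4 did not pass.

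Among gains, the largest after the Srsf1 event was an alternative first exon of Ncor1, a nuclear receptor corepressor, at chromosome 11, 62359761 to 62359934, which rose from 33.3% ± 3.10 to 64.7% ± 8.51 (limma difference 31.4 points, SE 4.45, adjusted p = 0.00112). Retention of a 210-nucleotide intron of Hnrnpdl, an RNA-binding hnRNP-like protein, rose from 7.29% ± 0.552 to 36.5% ± 11.8 (chromosome 5, 100036652 to 100036861; limma difference 29.3 points, SE 5.76, adjusted p = 0.00259). Coding cassette exons rose in Bod1l, from 31.5% ± 6.37 to 56.2% ± 6.75, and in Ktn1, which encodes the kinesin-binding protein kinectin, from 63.2% ± 8.34 to 84.9% ± 6.18. They also rose in the ubiquitin ligase gene Rnf138 (49.8% ± 3.92 to 69.5% ± 8.76) and Arfip1 (42.9% ± 4.91 to 62.2% ± 9.00). A first exon of Wfdc2 rose from 4.57% ± 1.70 to 25.5% ± 5.56. Other first exons of Wfdc2 were listed as falling (differences of medians −16.09 and −19.28 points), so this switch also counts among the losses. For Dlg1, a scaffold protein of cell polarity, a mutually exclusive exon rose from 55.3% ± 6.94 to 78.2% ± 10.9, with 1 mutant library within the control range. An alternative 3′ splice site of Hmgb1 (75.1% ± 13.0 to 99.4% ± 1.23) and a first exon listed under H2-Q4 (8.80% ± 9.17 to 27.2% ± 10.4) are uncertain, because both genes have near-identical copies in the genome and the H2-Q4 exon lies in H2-Q1 in the annotation used here. Without control 2 or control 7, the H2-Q4 event no longer passed (limma adjusted p = 0.0699 and 0.0722, differences 15.5 and 14.8 points against 22.3 with all libraries, as medians).

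Among losses, an alternative 5′ splice site of Elp3, the catalytic subunit of Elongator, fell from 87.3% ± 3.95 to 48.8% ± 5.61 (chromosome 14, 65592925 to 65592981; limma difference −38.5 points, SE 3.42, adjusted p = 0.000214). The alternative last exon of Pbdc1 fell from 82.6% ± 7.76 to 43.3% ± 8.57. Coding cassette exons fell in Prrc2b (57.5% ± 9.02 to 24.2% ± 5.61), Fopnl, which encodes a centrosomal protein (63.4% ± 2.29 to 32.9% ± 3.33), Tulp2 (95.5% ± 2.12 to 66.1% ± 7.59) and the histone deubiquitinase gene Usp3 (99.03% ± 1.68 to 71.9% ± 10.9). A cassette exon in the 5′ untranslated region of Ogdhl fell from 70.5% ± 12.7 to 37.8% ± 7.13. Intron retention fell in Znhit6, a factor for assembly of small nucleolar ribonucleoproteins (84.2% ± 6.11 to 53.7% ± 3.95), and in the gene listed as AC152939.2 (79.7% ± 6.4 to 47.1% ± 11.5). A cassette exon of Tbc1d9b had the largest difference of medians among losses, but its control libraries were spread (70.1% ± 20.7 against 40.04% ± 11.3 in the mutants) and its groups overlapped. Its difference of medians was −44.6 points with all libraries, −26.8 without control 1 and −27.1 without control 2, where it no longer passed (limma adjusted p = 0.0593 and 0.0662).

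**Figure D3:**
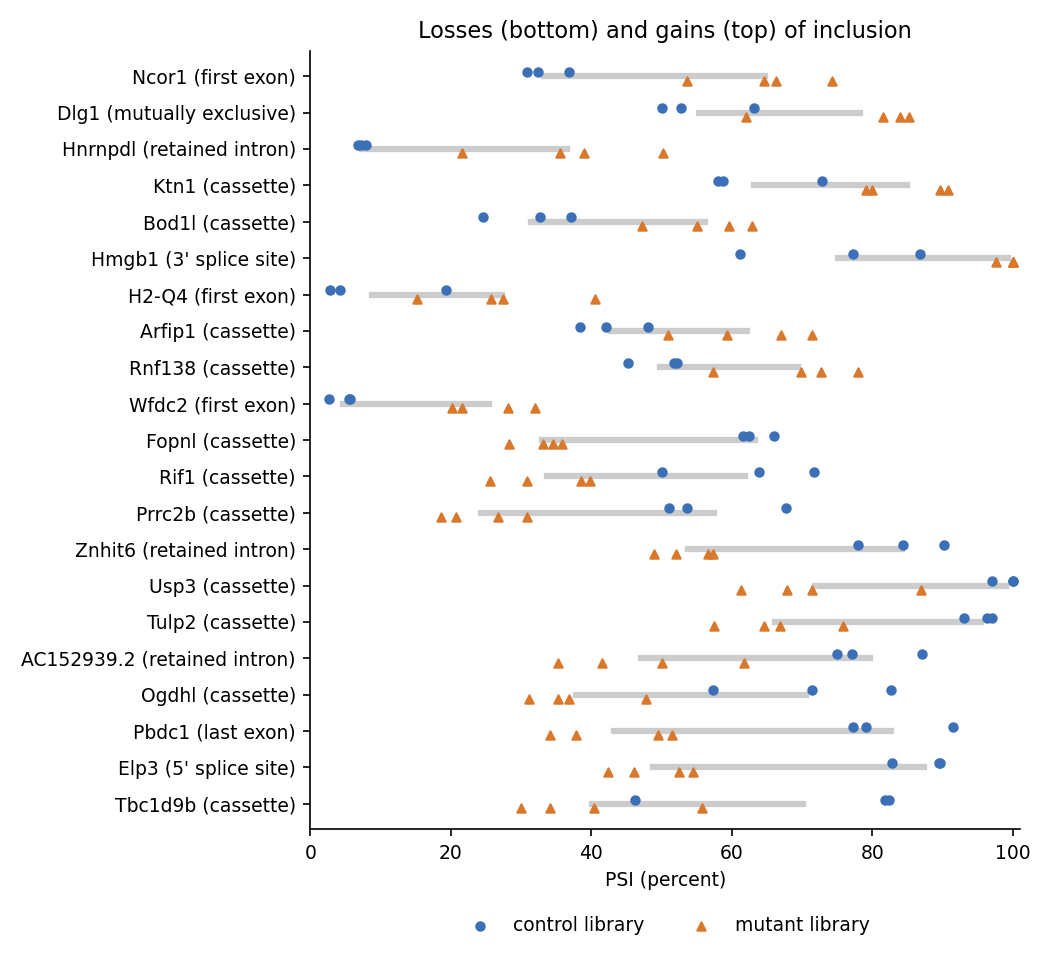
PSI (percent) in each control library (circles) and mutant library (triangles) for events among the largest gains and losses that are described here, other than that of Srsf1, with a grey bar from the control mean to the mutant mean. The 4 mutants of the Elp3 5′ splice site and of Fopnl lie below all 3 controls, and Tbc1d9b, Dlg1 and H2-Q4 have overlapping groups.

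Genes of RNA processing were present in the table. In the fixed list of 29 SR proteins and related factors, 4 genes had changed events, with 6 events lower and 1 higher. Besides Srsf1 these were Srsf5, in which retention of an intron fell from 23.6% ± 3.44 to 10.96% ± 3.92, Srsf10, in which an alternative last exon fell from 71.5% ± 0.244 to 62.8% ± 2.2, and Srrm2, a scaffold of nuclear speckles. An alternative 3′ splice site of Srrm2 fell from 45.2% ± 2.18 to 25.3% ± 7.88. On the logit scale the Srsf10 event did not pass (limma adjusted p = 0.0657). In the list of 48 hnRNPs and other splicing regulators, 8 genes changed (Celf2, Hnrnpa2b1, Hnrnpc, Hnrnpd, Hnrnpdl, Hnrnph3, Rbm5 and Taf15), with 7 events lower and 2 higher. A coding exon fell in Celf2 from 83.7% ± 4.98 to 66.0% ± 7.59, in Hnrnph3 from 72.5% ± 1.02 to 57.0% ± 8.78, and in Hnrnpd from 58.9% ± 0.806 to 43.2% ± 4.23. Of 40 core spliceosome genes only U2af2, which binds the polypyrimidine tract, was listed, with a first exon at 96.6% ± 2.5 and 90.2% ± 2.58; it lost significance without control 1 or control 2 (limma adjusted p = 0.0639 and 0.0875).

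Regulators of chromatin and of cell structure formed the next groups. In the list of 68 chromatin and transcription regulators, 8 genes had changed events, among them Brd8, Ehmt2, Ezh2, Kdm5a, Kdm5c and Ncor1, with 6 events lower and 3 higher. A coding exon of Ezh2, the catalytic subunit of Polycomb repressive complex 2, rose from 60.3% ± 10.0 to 79.7% ± 6.36 (chromosome 6, 47541845 to 47541970; limma difference 19.4 points, SE 5.11, adjusted p = 0.00755). An exon of the histone H3 demethylase gene Kdm5c fell from 93.5% ± 5.96 to 69.4% ± 7.71. In the list of 71 adhesion, cytoskeleton and epithelial isoform genes, 7 changed, among them Add1, Cttn, Dnm1l, Enah, Flna and Pkp4, with 7 events lower and 1 higher. Exons fell in the junction protein gene Pkp4 (35.1% ± 3.96 to 15.8% ± 4.52), in Dnm1l, a GTPase of mitochondrial fission (36.3% ± 9.06 to 19.6% ± 2.49), and in the actin regulator Enah (32.3% ± 5.18 to 19.97% ± 4.92, with 1 mutant library within the control range). The Dnm1l difference of medians was −20.5 points with all libraries and −13.1 without control 1 (limma adjusted p = 0.0205).

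The fixed lists for proliferation, death and lineage had few genes with listed events, and genes of these kinds outside the fixed lists were not counted. Of 65 cell cycle genes, 2 changed, both components of the chromosomal passenger complex: a coding exon of Incenp fell from 98.6% ± 1.78 to 86.4% ± 5.48, and one of Birc5, which encodes survivin, from 90.9% ± 5.59 to 79.9% ± 3.31. The Birc5 difference of medians was −13.6 points with all libraries and −8.94 without control 1 (limma adjusted p = 0.0402). Birc5 was also the single changed gene among 41 cell death genes and among 42 dental epithelial genes. Among 64 DNA replication and repair genes, an exon of Rif1, a regulator of replication timing and break repair, fell from 61.8% ± 10.99 to 33.7% ± 6.70 (chromosome 2, 52116668 to 52116745; limma difference −28.2 points, SE 5.48, adjusted p = 0.00245). Among 28 genes with textbook accounts of SRSF1-dependent splicing, only Pkm was listed: one of its mutually exclusive exons was at 6.65% ± 1.19 in the controls and 2.65% ± 0.567 in the mutants (limma adjusted p = 0.0453), and it no longer passed when any of the 7 libraries was left out (limma adjusted p from 0.0509 to 0.141). Its difference of medians then lay between −4.43 and −3.25 points, against −3.80 with all libraries. It passed on the logit scale (limma adjusted p = 0.00229) and by the DRIMSeq corrected p in the authors' deposited table (0.00295). None of the 76 signalling genes, the 22 dental mesenchyme markers or the 20 blood and endothelial markers had a listed event, by limma or by the authors' DRIMSeq test. Adjusted over the list alone, each list kept the same number of changed events. That outcome was fixed in advance, because every listed event of these lists had already passed. Of 593 genes in the 13 lists, 32 changed, and the table holds no set of tested but unlisted genes against which enrichment could be measured. In the authors' deposited table, the DRIMSeq corrected p lay between 0.0515 and 0.0951 for 9 of the 40 named events, those of H2-Q4, Arfip1, Rnf138, U2af2, Srsf10, Birc5, Srrm2, Dnm1l and Tbc1d9b.

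Lengths of the changed cassette exons ran from 12 to 680 nucleotides, with a median of 114. Of the 169 exons, 100 had a length divisible by 3 (59.2%, against 33.3% for random lengths; exact two-sided binomial p = 7.09e-12). The share was 58.0% among the exons that fell and 65.4% among those that rose, a difference within chance by Fisher's exact test (two-sided p = 0.523). No unlisted exons serve as a reference, so the excess over random lengths cannot be tied to the Srsf1 deletion. By annotation, 128 of the exons that fell and 21 of those that rose were coding, and 7 and 1 lay in 5′ untranslated regions. Another 5 and 1 belonged to non-coding transcripts, and 3 and 3 occurred in transcripts annotated for nonsense-mediated decay but in no protein-coding transcript. Of these last, the 3 that rose were in Thrap3, Npepps and Phf14.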

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

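Among the tests in this part, that of a shallower library was chosen after the result was seen. Of the 40 named events, 3 had 1 mutant library far from the other 3, where chance alone would give about 1 in 20. For the mutually exclusive exon of Dlg1, mutant 9 had a PSI of 61.96% and the other mutants 81.58 to 85.19% (gap over range 0.845). For the cassette exon of Enah, mutant 9 had 27.33% and the others 17.14 to 17.95% (gap over range 0.921). For the alternative 3′ splice site of Hmgb1, mutant 5 had 97.55% and the others 100% (gap over range 1), a gap of few points at the upper end of the scale.

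In Dlg1 and Enah, mutant 9 was the library nearest to the controls, and the same held in 136 of the 277 events other than that of Srsf1. Relative to the mean change of the other mutants, the changes of mutant 9 had a scale of 0.717 (95% bootstrap interval over genes 0.670 to 0.763), against 0.895 for mutant 3, 1.07 for mutant 5 and 1.27 for mutant 4. Noise from a shallower library would by itself scatter values without shrinking them on average, and the interval lay below 1. This cannot decide on noise as a cause, because the events were selected on these same libraries and depth per library is unknown. Cells that escaped recombination could shrink all changes of a library by one factor: in mutant 9 the scale over falling events minus that over rising events was 0.0458 (interval −0.120 to 0.200), as that would need, but in mutant 5 it was −0.147 (−0.268 to −0.0231), and the Srsf1 to Vezf1 junction did not follow the same order, with the lowest mutant PSI (44.74%) in mutant 4, the library with the largest changes. Incomplete recombination therefore cannot be told apart from a difference between animals in the response, for which no label exists.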

How the results depend on the processing

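Among the settings here, a control PSI of 20 to 80%, 1 event per group of overlapping events, the exclusion of first, last and mutually exclusive exons, and all settings for cassette direction were chosen after seeing the data. The 266 changed events became 1 with the authors' JuncBASE corrected p (a Klc1 first exon, named after its values were seen), although 244 events had a raw JuncBASE p below 0.05; the cause was not tested. The count was 275 on the logit scale, 192 and 260 with a minimum of 10 and 5 points, 215 at an adjusted p of 0.01, 214 by the DRIMSeq corrected p, 239 to 266 without 1 library, and 266 without mutant 9. The percentage of changed events that fell ranged from 74.2 to 83.2%, that of cassette exons from 71.4 to 90.8%, the median size from 12.9 to 15.1 points, the Srsf1 difference of medians from 47.8 to 57.6 points, the cassette share from 59.9 to 66.5%, the share of exons divisible by 3 from 58.7 to 65.2%, and the changed list genes from 22 to 25, against 32. Of 39 named events other than Srsf1, 35 passed with each of the 7 libraries left out; H2-Q4, Pkm, U2af2 and Tbc1d9b did not. By the DRIMSeq corrected p, 9 named events lay above 0.05 (H2-Q4, Arfip1, Rnf138, U2af2, Srsf10, Birc5, Srrm2, Dnm1l and Tbc1d9b), and on the logit scale Srsf10 did. The alternatives planned for read counts (a quasi-binomial model, a read minimum, library-size normalization) were not run, because the table holds none, and requiring a value in every library removed no event. No paired analysis was possible because the groups share no replicate number. Without read numbers, no limit set by depth could be given.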

Other observations

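Among the tests in this part, those of room to fall, of overlapping events, of base composition and of nonsense-mediated decay exons were chosen after the result was seen, as were the count of splits and the number of tests implied by the corrected p-values. Genes in the next paragraph were also chosen after their values were seen.

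Several genes had more than 1 changed event. In Hnrnpdl, retention of a 210-nucleotide intron rose, and an alternative 3′ splice site next to it, at chromosome 5, 100036196 to 100036651, fell from 98.8% ± 0.83 (SD, n = 3) to 72.2% ± 9.57 (SD, n = 4; limma adjusted p = 0.00193). In Srrm2, the 3′ splice site, a retained intron (38.1% ± 1.03 to 21.1% ± 6.67) and 2 cassette exons (91.9% ± 4.11 to 81.6% ± 4.40, and 22.6% ± 7.02 to 9.87% ± 4.32) all fell by limma. In Dnm1l 2 exons fell, that of 33 nucleotides from 57.2% ± 11.1 to 34.8% ± 7.12. In Kdm5c a further exon fell from 96.8% ± 3.50 to 86.0% ± 3.95, and in the actin crosslinker Flna an exon of 24 nucleotides fell from 57.9% ± 6.25 to 38.3% ± 6.0. Among exons that were nearly always included in the controls, inclusion fell in Usp3, Trnau1ap (98.1% ± 0.603 to 74.0% ± 5.99), Zmym3 (97.53% ± 2.57 to 74.7% ± 8.85) and Ino80e (98.8% ± 2.14 to 77.1% ± 6.43). Of 13 changed cassette exons with a control PSI under 20%, 8 fell and 5 rose (exact two-sided binomial p = 0.581). Inclusion fell in Adgrl2 (9.89% ± 1.06 to 2.58% ± 0.809) and Rer1 (14.4% ± 1.98 to 5.69% ± 1.27) and rose in Ptprk (0.607% ± 1.05 to 7.50% ± 2.11) and Mmadhc (1.97% ± 0.958 to 6.87% ± 1.33).

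Most changed cassette exons fell, which could follow from exons near full inclusion having no room to rise, or from overlapping events counted more than once. Among exons with a control PSI of 20 to 80%, 71.4% of 56 still fell (exact two-sided binomial p = 0.00184), and with 1 exon per group of overlapping events 83.9% of 155 did (exact p = 2.58e-18), so neither accounts for the whole excess. Part of it stays open, because how the authors chose the listed events may favour some directions. By junction class, 91.0% of 89 exons with an unannotated junction fell against 77.5% of 80 with known junctions (Fisher's exact test, two-sided p = 0.0187). All 61 exons with a control PSI of at least 95% fell, and 44 of them had an unannotated junction. The gap between the classes is therefore not separate from room to fall.

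SRSF1 is known to bind purine-rich GGA motifs, and exons that lost inclusion may carry more of them. In 1 exon per group of overlapping events, the 130 that fell held 3.64 ± 1.6 GGA trimers per 100 nucleotides (SD over exons) against 2.72 ± 1.64 in their flanking exons, a mean difference of 0.919 (SEM 0.163; 96 of 130 above; sign-flip permutation p = 1e-05, the smallest these permutations can give). The 25 that rose went the other way, with 0.974 ± 1.35 against 2.35 ± 1.09 (difference −1.38, SEM 0.384; 4 of 25 above; sign-flip permutation p = 0.00131). Exons that fell exceeded those that rose by 2.67 trimers per 100 nucleotides (SE 0.304, permutation p = 2e-05, the smallest these permutations can give), and by 2.33 (SE 0.270, permutation p = 2e-05, the same limit) after subtracting the density that each exon's own bases would give in random order, which argues against base composition. These results suggest, as a hypothesis, that many of the exons that fell depend on direct SRSF1 binding; mapping that binding, or mutating the GGA motifs in splicing reporters, would decide it, and neither the selection of the listed exons nor an effect of tamoxifen itself is excluded.

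Exons found in transcripts annotated for nonsense-mediated decay, but in no protein-coding transcript, were 11.5% of the 26 cassette exons that rose (Thrap3, Npepps and Phf14). They were 2.1% of the 143 that fell (Lsm5, Bclaf1 and Srrm2), with a two-sided p = 0.0474 by Fisher's exact test. With 3 exons on each side, 1 exon more or less could change the call, so this is a lead to follow and no more.

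Of the 35 ways to split the 7 libraries into 3 and 4, only the real one (1 of 35) gave as many as 266 events by limma. The highest of the others gave 146, with mutants 3, 4 and 5 set against the controls and mutant 9. Chance cannot be excluded in this way, because the events were selected on the real split.

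The authors' deposited table also carries a trace of what was tested. If the DRIMSeq corrected p-values are Benjamini-Hochberg values within each event type, the number of tests times the raw p divided by the corrected p is a whole rank, except where a corrected value was carried over from an event that is not listed. The smallest number of tests at which at least 70% of the distinct corrected values gave whole ranks is 2778 for cassette exons (119 of 121 whole within 1e-05), 27301 for retained introns (12 of 16), 7185 for alternative 3′ splice sites (4 of 5) and 5980 for alternative 5′ splice sites (8 of 8). On these numbers, 6.23% of tested cassette exons were listed, against 1.65% of 1875 first exons, 1.76% of 1474 last exons, 0.134% of 5′ splice sites, 0.0835% of 3′ splice sites and 0.0623% of retained introns. Coordinate cassettes were close, with 6.47% of 139 (Fisher's exact test against cassette exons, two-sided p = 0.857). Mutually exclusive exons were higher, with 18.2% of 44 (p = 0.0059 by the same exact test). The numbers of these 2 types rest on 4 distinct corrected values each. Several of the listed mutually exclusive exons are versions of 1 Dlg1 switch with overlapping exons, which the test counted as separate. The ranks also reach 179 for cassette exons and 31 for retained introns, beyond the 173 and 17 listed.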
